A study of Mus musculus with 13 samples.

How the data were processed

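RNA was measured in 9 libraries of oligodendrocyte-lineage cells cultured from C57BL/6 mouse brain. Per the labels, oligodendrocyte precursor cells (OPCs) were grown with PDGF and NT-3, and immature oligodendrocytes (iOLs) were collected on day 2 after thyroid hormone was added and PDGF removed. Groups were taken from the sample titles, since the genotype entry reads the same for controls and cKO samples. Per the labels, total RNA was made into libraries with a stranded polyA kit above 100 ng of RNA and with an amplifying kit below that, and which library had which kit is not stated. Antisense genes are therefore given as uncertain, and so are genes with near-identical copies, whose reads the table cannot tell apart. The labels do not say whether replicates are separate animals or cultures, so the p-values measure the spread between these samples. The chromatin immunoprecipitation samples of the series were not analysed here.

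The deposited table holds raw counts, whole numbers of reads per gene. Per the labels, the authors trimmed reads with cutadapt 1.14, aligned them to mm10 with STAR 2.6.0 and counted them with featureCounts of Subread 1.6.2. The table has 13549 genes, each with a count of at least 1 in every library and of 10 or more in at least 4 libraries, so genes at 0 in any library were removed before deposit and were not analysed here. A second header line was left out. Of the symbols 97.9% matched the gene table used for positions. Total counts were 17417529, 19680398, 18327207, 18567690, 19618603, 17958893, 17899327, 17949606 and 18361805, in the order control OPC 1 and 2, cKO OPC 1 to 3, control iOL 1 and 2 and cKO iOL 1 and 2. Exact 95% binomial intervals of ratios are given for genes with few counts in a group. They pool the libraries of a group, so they cover counting error alone and not the spread between libraries.

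Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The 9 libraries were fitted together with 4 group means, TMM factors and edgeR's quasi-likelihood test, with a filter by expression at a minimum count of 10, which removed no gene. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The common dispersion was 0.0265, a biological coefficient of variation of 16.3%, with 5 residual degrees of freedom. The comparisons were Eed cKO against control in OPCs and in iOLs, iOLs against OPCs in controls and in cKO cultures, and the difference between these. Principal components used log2 CPM with a prior count of 2. Values after ± are standard errors of log2 fold changes unless marked SD. Each was derived from the test, as the size of the log2 fold change over the square root of its F statistic. For genes with few counts in a group, such as Foxf1 and Cdkn2a, they are narrower than the intervals of counting error alone. The intervals are the safer guide there.

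The groups, comparisons, tests, gene lists and alternatives, and the rule for the genes to name, were chosen before the data were examined. Named are Eed and the other core PRC2 genes, the 10 genes with the largest fold each way in the cKO comparisons and the first 8 in the others, up to 4 members of each list, and 11 further lineage, signalling and cell-cycle genes, of which a part is not reported here. Genes named by fold had an adjusted p under 0.05, at least 5 CPM in the higher group and, except for the difference of differences, no overlap between the groups. Of 30 gene lists written, 27 had at least 5 measured members and were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. None of the symbols written for mitochondrial transcripts and for red blood cell genes is in the table, which does hold the globin gene Hbb-b1, and 3 of those for microglia are, so these lists were not tested.

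Alternatives were RLE size factors, no filter, at least 1 CPM in 4 libraries, only the groups compared, the replicate number as a block, postnatal day as a term, DESeq2, leaving out each library, and for the lists an estimated correlation and fry. In a group of 2, leaving 1 library out leaves a single one, whose own differences cannot be told from those of its group. On simulated data with 200 of 13549 genes changed, the test found 65.4% and 96.2% of 2-fold and 4-fold changes in the OPC comparison, 52.6% and 89.4% in the iOL comparison and 24.6% and 81.4% in the difference of differences. The mean false share of calls ran from 5.42% to 7.53% over the comparisons and from 6.76% to 8.62% with postnatal day as a term, above the nominal 5%, and the highest share in a single simulation was 10.4% and 11.1%. A raised list was called by camera in 5 of 5 simulations of each comparison. The simulated counts were independent between genes, with the same dispersion of a gene in all libraries and no effect of postnatal day. The measured libraries differed in spread. The chi-square per degree of freedom was 106 between the control OPC libraries and 6.48 between the control iOL libraries. The simulated shares therefore describe simpler data than those measured.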

Results

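Gene expression was measured by RNA sequencing in cultured mouse oligodendrocyte precursor cells (OPCs) and in immature oligodendrocytes (iOLs), the cells that OPCs become over 2 days in differentiation medium. Each stage was studied in control cells and in cells from conditional knockouts (cKO) of Eed, which encodes a core subunit of Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates histone H3 at lysine 27 and keeps developmental genes silent. The count table held 9 libraries, 2 of control OPCs, 3 of Eed cKO OPCs, 2 of control iOLs and 2 of Eed cKO iOLs. The brains were taken at postnatal day 7 for OPC control replicate 1 and OPC Eed cKO replicates 1 and 2, and at day 6 for the other 6 libraries. Total counts ran from 17417529 in OPC control replicate 1 to 19680398 in OPC control replicate 2, and the 7 other libraries lay between them. The series also has chromatin immunoprecipitation samples for Suz12 and Eed, which were not analysed here.

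The first principal component of the log2 CPM (counts scaled to the depth of each library) held 64.9% of the variance and separated iOLs from OPCs. The second held 16.2% and separated Eed cKO from control libraries at both stages. The third, with 8.16%, placed both day 6 OPC libraries at −34.6 and −18.1 and the 3 day 7 OPC libraries between 2.6 and 25.7. The day 6 libraries OPC control replicate 2 and OPC Eed cKO replicate 3 had a Spearman rho of counts of 0.990. OPC Eed cKO replicate 3 was less close to OPC Eed cKO replicates 1 and 2 (0.982 and 0.981), which are of day 7. OPC Eed cKO replicates 1 and 2 had a rho of 0.997 with each other. Their chi-square per degree of freedom was 7.67, against 47.3 and 47.4 with replicate 3. The labels do not say whether these libraries come from separate animals or cultures. OPC control replicate 1 stood apart on the fourth component (5.31%) at −33.9. It held 5380 CPM of Lars2 and 4456 CPM of Mir6236, against at most 381 and 172 CPM in any other library. It also held 3467 CPM of Mbp, a myelin protein gene, against 483 to 1424 in the other 4 OPC libraries, and 2877 CPM of the globin gene Hbb-b1 against 562 to 1044.

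**Figure D1:**
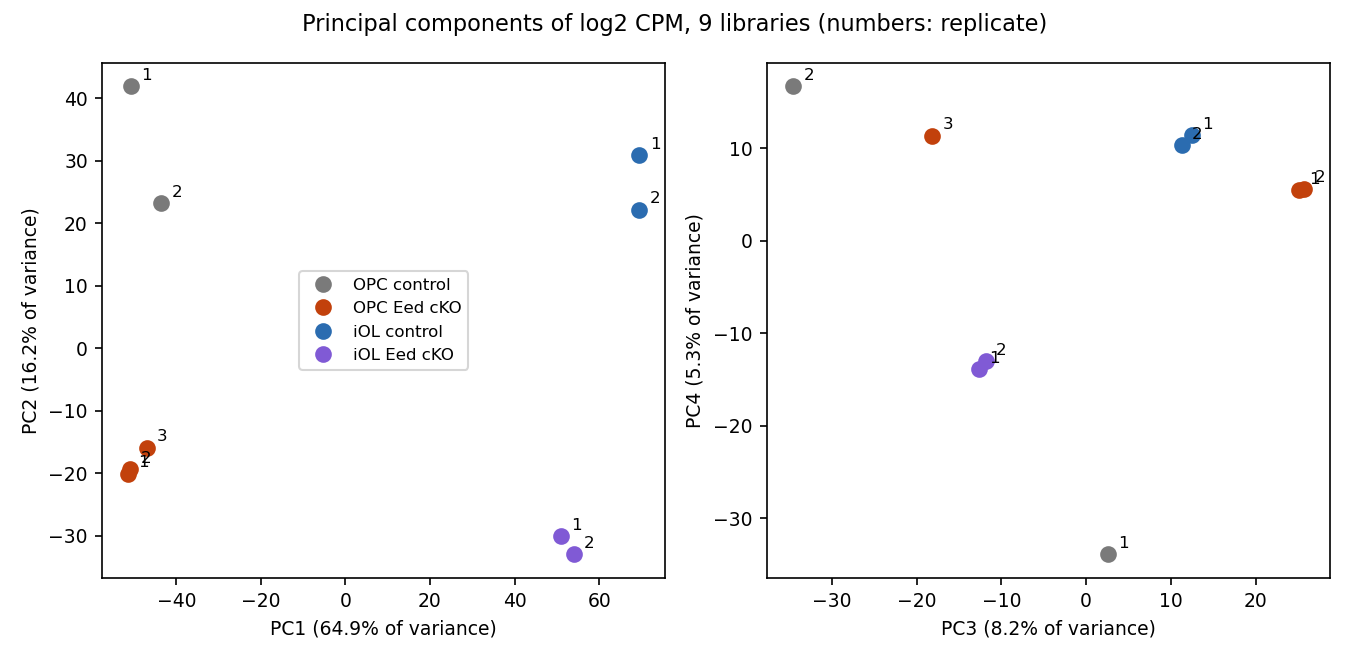
Scores of the 9 libraries on principal components 1 and 2 (left) and 3 and 4 (right) of log2 CPM, with the percent of variance on each axis; each point is a library, coloured by group and numbered by replicate. The first component (64.9%) separates the stages, the second (16.2%) the genotypes, and OPC control replicate 1 lies at −33.9 on the fourth.

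Eed itself (chromosome 7, 89954654 to 89980976, mm10) was lower in every cKO library than in every control library of its stage. Its level was 21.7 and 16.8 CPM in control OPCs against 13.3, 11.8 and 12.5 CPM in cKO OPCs, and 18.0 and 21.2 CPM in control iOLs against 14.6 and 12.1 CPM in cKO iOLs. The log2 fold change was −0.62 ± 0.17 (SE) in OPCs and −0.55 ± 0.18 in iOLs, and neither passed the test across all genes (edgeR adjusted p = 0.0847 and 0.0973, with ranges over the other settings of 0.0121 to 0.278 and 0.0393 to 0.459). Counts are summed over the whole gene and the deleted part is not given in the sources used here, so the level of the deleted exons was not measured. Suz12, Ezh1 and Ezh2, the other core PRC2 genes, passed the test in neither stage, with log2 fold changes between −0.12 and 0.22.

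Eed cKO OPCs were compared with control OPCs to find the genes that differ in proliferating precursors. The mesodermal transcription factor gene Foxf1 rose most, from 3 counts in the 2 control libraries to 906 in the 3 cKO libraries. The ratio per total count, scaled by the TMM factors, was 193 (exact 95% interval of counting error alone 65.9 to 939). Its log2 fold change was 7.48 ± 0.38 (edgeR adjusted p = 4.1e-05). Cdkn2a, which encodes the cell-cycle inhibitor p16 and the p53 activator p19ARF, rose from 11 to 1158 counts, a ratio of 67.3 (counting interval 37.5 to 135; log2 6.04 ± 0.38, adjusted p = 8.9e-05). Lef1, a transcription factor gene and target of Wnt signalling, rose 7.41-fold (log2 2.89 ± 0.21, adjusted p = 0.00014). Myo7a, an unconventional myosin gene, fell by 3.38 ± 0.33 on the log2 scale (adjusted p = 0.00068), from 10.4 ± 1.61 CPM (SD, n = 2) to 0.999 ± 0.455 CPM (SD, n = 3).

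The other largest increases were of Tbx18 (log2 6.52 ± 0.49), Osr2 (6.35 ± 0.78), Hmx1 (5.66 ± 0.49) and Smoc2 (5.61 ± 0.33). They were followed by Vax2os (5.52 ± 0.48), Pou4f1 (5.37 ± 0.34), She (5.30 ± 0.38) and Tbx15 (4.86 ± 0.35), with edgeR adjusted p from 6.3e-05 (Smoc2) to 0.0024 (Osr2). Tbx18, Osr2, Hmx1, Pou4f1 and Tbx15 encode transcription factors of limb, head, sensory neuron and connective tissue development, and Smoc2 a secreted matrix protein. Vax2os is an antisense gene, and its reads cannot be told from those of its partner in a library whose kit does not mark strand. Nkx2-1, a forebrain patterning factor (log2 −1.94 ± 0.32), and Agt, which encodes angiotensinogen and is made by astrocytes (−1.88 ± 0.37), fell. So did S100a13 (−1.37 ± 0.28), Gamt (−1.27 ± 0.21), the last enzyme of creatine synthesis, Neu4 (−1.25 ± 0.26), Lpar1 (−1.17 ± 0.27), S100a1 (−1.14 ± 0.24), Resp18 (−1.11 ± 0.23) and Comtd1 (−1.08 ± 0.20). These 9 decreases had adjusted p from 0.013 to 0.049. Each call ended when OPC control replicate 1, OPC Eed cKO replicate 1 or OPC Eed cKO replicate 2 was left out. The adjusted p then ran from 0.0504 (Nkx2-1 without OPC Eed cKO replicate 1) to 0.197 (Lpar1 without OPC Eed cKO replicate 1). The increases named here kept their calls without each library in turn.

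In all, 399 genes were higher and 41 lower in Eed cKO OPCs out of 13549 tested. Of these 118 and 4 changed by over 4-fold. At an unadjusted p under 0.05 there were 3477. Across all genes the cKO difference within postnatal day 7 (2 cKO libraries against 1 control) and within day 6 (1 against 1) had a Pearson r of 0.556. The Foxf1 log2 difference, for example, was 6.25 on day 7 and 6.47 on day 6, and that of Myo7a −2.94 and −3.90. Leaving out a control library leaves 1 control of a single postnatal day, whose own differences cannot be told from those of the genotype. The counts of calls depended on single libraries. They were 202 higher and 10 lower without OPC control replicate 1 and 1862 and 2073 without OPC control replicate 2. They were 161 and 3 without OPC Eed cKO replicate 1, 161 and 4 without replicate 2, and 1334 and 810 without replicate 3. With postnatal day as a term they were 848 and 534, which holds a share of higher calls of 61.4% against 90.7%.

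Developmental genes were the gene group with the smallest p in Eed cKO OPCs. Of 45 measured members of a list of developmental transcription factors known as PRC2 targets, 19 rose, 1 fell and 25 did not pass (27 and 3 passed adjusted over the list alone), with a mean log2 fold change of 1.62 (camera adjusted p = 1.1e-19). Foxc1 (log2 3.28 ± 0.32), a factor of the meninges and vessels, was among them. Of 10 measured Hox genes, which set position along the body axis, 4 rose and 6 did not pass (9 rose adjusted over the list alone, camera adjusted p = 6.5e-09), led by Hoxa5 (4.09 ± 0.50) and Hoxb6 (3.23 ± 0.38). As written, these lists held 98 developmental factors and 39 Hox genes. The table holds only genes of 10 or more counts in at least 4 libraries. A gene under 10 counts in every control library, such as Hoxb6, is held only if cKO libraries reach 10. The direction and p of these 2 lists are therefore in part set by that limit. Of 19 canonical Wnt target genes 4 rose and 15 did not pass (8 adjusted over the list alone, camera adjusted p = 8.4e-07), namely Lef1, Sp8 (3.55 ± 0.40), Nkd1 (0.76 ± 0.11) and Rnf43 (0.67 ± 0.11). Nkd1 and Rnf43 encode inhibitors of the pathway, and Axin2, a further target, was at 0.17 ± 0.19 (adjusted p = 0.58). The neuron marker list was higher too, with 4 of 25 rising and 21 not passing (11 adjusted over the list alone, camera adjusted p = 8.1e-07). These 4 were the GABA neuron genes Gad2 (2.55 ± 0.19), Slc32a1 (2.41 ± 0.31) and Dlx2 (2.43 ± 0.50), and Neurod1 (2.35 ± 0.31). The adjusted p with an estimated correlation was 0.0805 for the developmental factors, 0.142 for Hox genes, 0.116 for Wnt targets and 0.391 for neuron markers, so these calls hold with the preset correlation and were lost with an estimated one. Without OPC control replicate 1, OPC Eed cKO replicate 1 or OPC Eed cKO replicate 2 the call of Rnf43 ended at adjusted p = 0.0548, 0.0703 and 0.0540, and that of Dlx2 at 0.187, 0.106 and 0.0819.

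The inhibitor genes Cdkn2a, Cdkn2b and Cdkn1a rose, and the cell-cycle gene list was not called. Of 18 senescence and arrest genes 3 rose, 1 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0061, adjusted p = 0.142 with an estimated correlation). Beside Cdkn2a these were its neighbour Cdkn2b (log2 3.16 ± 0.36), Cdkn1a (2.65 ± 0.27), which encodes p21, and Gadd45g (−1.01 ± 0.18). All 38 cell-cycle and DNA replication genes failed to pass (camera adjusted p = 0.123), where edgeR gave 7 lower at an unadjusted p under 0.05 and DESeq2 called 0. Mki67, a marker of dividing cells, was at 0.47 ± 0.33 (adjusted p = 0.39). The call of the arrest list ended without OPC control replicate 2 (camera adjusted p = 0.165) and without OPC Eed cKO replicate 3 (0.0639), in a range over the settings of 0.00143 to 0.165, and that of Gadd45g ended without OPC control replicate 1 or OPC Eed cKO replicate 1 or 2 (edgeR adjusted p = 0.0517, 0.0934 and 0.0741).

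Signalling, matrix and endothelial lists were called higher as well. Of 37 Wnt ligands, receptors and modulators 1 rose, Wnt2b (log2 2.93 ± 0.36), and 36 did not pass (camera adjusted p = 0.015, adjusted p = 0.675 with an estimated correlation). Of 34 BMP and TGF-beta pathway genes 1 rose, Bmp5 (3.03 ± 0.50), and 33 did not (camera adjusted p = 0.031, adjusted p = 0.675 with an estimated correlation). Each of these counts was the same adjusted over the list alone. Of 20 Notch pathway genes 4 rose, Jag2 (1.20 ± 0.19), Hey2 (1.36 ± 0.25), Cntn1 (1.06 ± 0.19) and Hey1 (0.71 ± 0.15), and 16 did not pass (6 adjusted over the list alone, camera adjusted p = 0.020, adjusted p = 0.316 with an estimated correlation). Of 37 extracellular matrix genes 4 rose, Col9a1 (1.88 ± 0.17), Col11a1 (1.20 ± 0.17), Col18a1 (1.91 ± 0.37) and Thbs2 (1.51 ± 0.31), and 33 did not pass (12 adjusted over the list alone, camera adjusted p = 0.00041, adjusted p = 0.377 with an estimated correlation). Of 6 endothelial markers 2 rose, the VEGF receptors Flt1 (4.35 ± 0.40) and Kdr (1.22 ± 0.24), and 4 did not (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0061, adjusted p = 0.142 with an estimated correlation). Leaving out OPC control replicate 1 ended the calls of the Wnt, BMP, Notch and matrix lists (camera adjusted p = 0.898, 0.951, 0.135 and 0.0712). Leaving out OPC control replicate 2 ended those of the Notch and endothelial lists (0.0544 and 0.105), and leaving out OPC Eed cKO replicate 3 those of the Wnt, BMP, matrix and endothelial lists (0.268, 0.132, 0.0653 and 0.0639). Of the genes named here, Wnt2b, Jag2, Col9a1, Col11a1 and Flt1 kept their calls without each library, while each of Bmp5, Hey1, Hey2, Cntn1, Col18a1, Thbs2 and Kdr lost its call without OPC control replicate 1, with edgeR adjusted p from 0.0528 (Thbs2) to 0.120 (Hey1 and Kdr).

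Myelin, astrocyte and ribosomal protein lists were lower in cKO OPCs, with few called members. Of 19 myelin structural genes 1 fell, Cnp (log2 −1.01 ± 0.23, edgeR adjusted p = 0.046), and 18 did not pass (1 adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.675 with an estimated correlation), and Mbp was at −1.19 ± 0.49 (adjusted p = 0.17). Of 19 astrocyte markers Agt fell and 18 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0012, adjusted p = 0.675 with an estimated correlation). All 39 ribosomal protein genes failed to pass, with a mean log2 fold change of −0.42 (camera adjusted p = 2.8e-06, adjusted p = 0.675 with an estimated correlation). There edgeR gave 12 lower at an unadjusted p under 0.05 and DESeq2 called 0. These lists also set the 2 control libraries apart. The median log2 ratio of control replicate 1 over control replicate 2 was 0.86 for myelin genes, 0.82 for ribosomal protein genes and −1.17 for astrocyte markers. Lists called higher set them apart too, with medians of 1.05 for Hox genes, 0.49 for neuron markers, −0.27 for developmental factors, −0.40 for Wnt ligands and −0.36 for matrix genes. Without OPC control replicate 1 the camera adjusted p was 0.344 for myelin genes and 0.767 for ribosomal protein genes, the latter with the direction turned, and without OPC control replicate 2 it was 0.776 for astrocyte markers. Cnp lost its call without OPC control replicate 1 or OPC Eed cKO replicates 1 or 2 (edgeR adjusted p = 0.205, 0.194 and 0.107).

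The remaining lists were not called in OPCs. Members that passed were Tmem2 (log2 1.56 ± 0.13) and Gpr17 (−0.80 ± 0.18) among 19 differentiation-committed genes, Neu4 among 22 OPC genes. Among 15 BMP targets they were Msx1 (1.80 ± 0.30), Dlx2, Tbx3 (4.05 ± 0.86) and Hey1. Further ones were Icam1 (1.93 ± 0.33), Cxcl12 (1.50 ± 0.28) and Igfbp3 (−0.69 ± 0.15) among 22 secretory genes of senescent cells. Igf2 (4.43 ± 0.61) and Col6a2 (1.30 ± 0.24) among 16 pericyte, fibroblast and meningeal markers passed as well. So did Erbb3 (1.34 ± 0.19) among 14 Schwann and neural crest markers, and Nr4a2 and Egr3 (0.81 ± 0.18) among 20 immediate early genes. Camera adjusted p ran from 0.233 to 0.903 for these 7 lists. Of these genes Tmem2 and Erbb3 kept their calls without each library, and each other one lost its call without OPC control replicate 1 (edgeR adjusted p from 0.0587 for Igf2 to 0.187 for Dlx2). The mean and the median differed in sign for OPC genes (−0.03 and 0.10), BMP targets (0.46 and −0.10) and Schwann markers (0.08 and −0.22). Further lists had no member past the test over all genes. Adjusted over the list alone edgeR called 2 thyroid hormone response genes and 1 ependymal marker higher and 2 cholesterol synthesis genes lower. At an unadjusted p under 0.05 edgeR gave 2 higher and 1 lower of 12 PRC2 subunits, 5 and 5 of 24 cholesterol synthesis genes, and 3 higher of 10 thyroid hormone response genes. It gave 1 and 1 of 6 ependymal markers, 1 lower of 13 interferon-stimulated genes and 1 and 3 of 19 stress response genes. DESeq2 called 1 lower, 2 higher and 2 lower, 1 higher, 0, 0 and 1 higher of them. The mean and the median also differed in sign for the cholesterol list (0.06 and −0.01) and the stress response list (0.01 and −0.08).

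**Figure D2:**
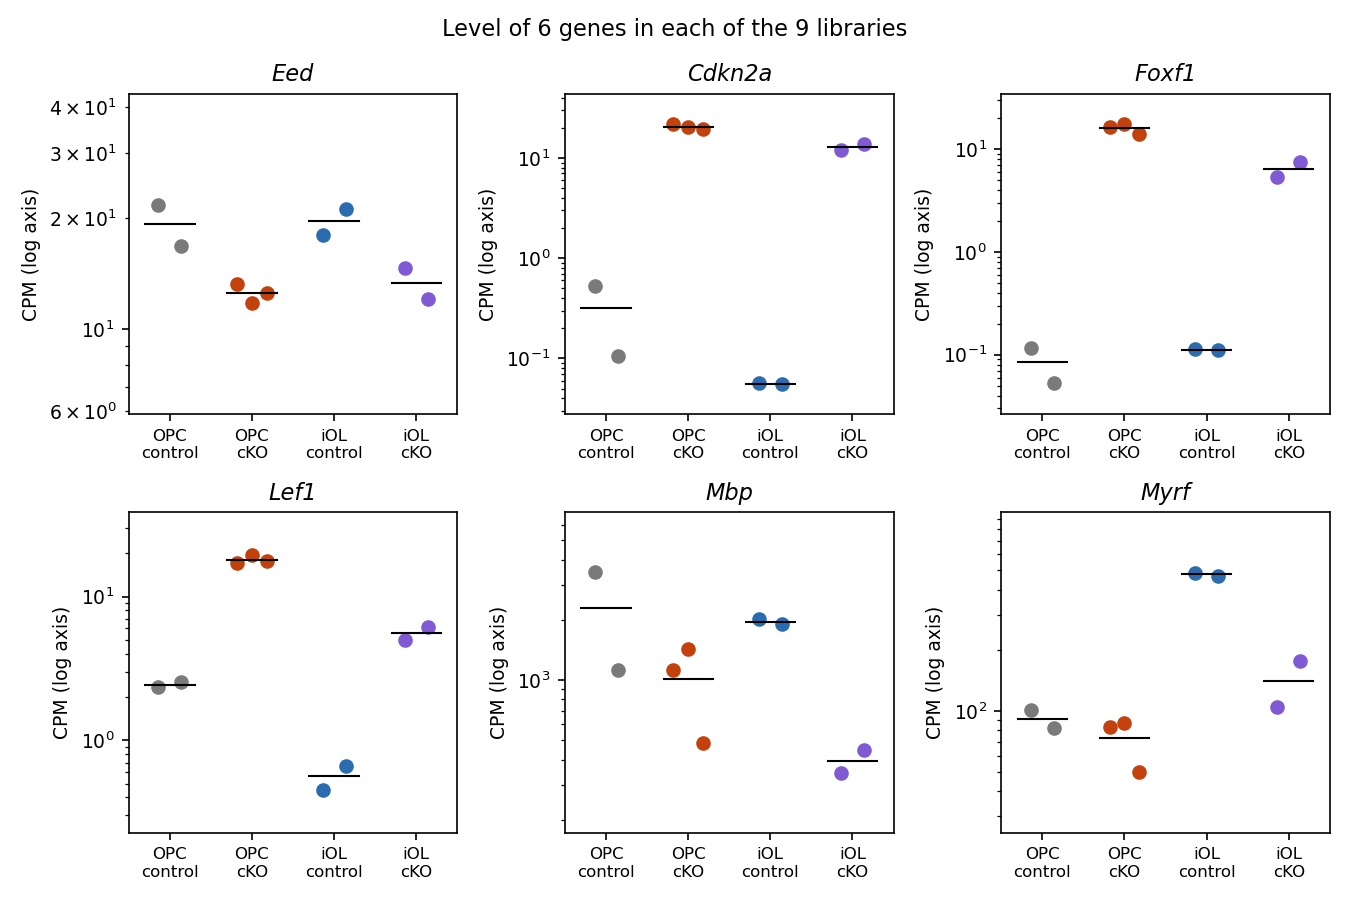
Level of Eed, Cdkn2a, Foxf1, Lef1, Mbp and Myrf in CPM on log axes, where each point is 1 of the 9 libraries and each bar a group mean. Cdkn2a lies between 12.1 and 22.0 CPM in the cKO libraries and at or below 0.527 CPM in the controls, and Myrf at 105 and 177 CPM in cKO iOLs against 485 and 469 CPM in control iOLs.

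Eed cKO iOLs were compared with control iOLs to find the genes that differ during differentiation. Cdkn2a rose most, from 2 counts in the 2 control libraries to 488 in the 2 cKO libraries, a ratio of 231 (exact 95% interval of counting error alone 63.5 to 1909; log2 7.68 ± 0.50, edgeR adjusted p = 0.00021). Mbp dropped from 1964 ± 72.5 to 396 ± 72.3 CPM (SD, n = 2 and 2; log2 −2.31 ± 0.57, adjusted p = 0.031), and Cnp, a myelin enzyme gene, from 1420 ± 16.1 to 393 ± 100.3 CPM (log2 −1.85 ± 0.26, adjusted p = 0.0028). Myrf, the transcription factor gene that drives myelin gene expression, dropped from 477 ± 11 to 141 ± 50.6 CPM (log2 −1.76 ± 0.30, adjusted p = 0.0066). The call of Mbp ended without any 1 of the 4 iOL libraries, at adjusted p = 0.131 and 0.102 without control replicates 1 and 2 and 0.215 and 0.139 without cKO replicates 1 and 2, and that of Myrf ended without iOL Eed cKO replicate 1 (adjusted p = 0.0584).

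Among genes of at least 5 CPM in the higher group, the other largest increases were of Nov (log2 6.13 ± 0.78), a secreted matricellular protein gene also called Ccn3, Foxf1 (5.77 ± 0.39), Tbx15 (5.13 ± 0.37) and Nkx6-1 (5.08 ± 0.50). They were followed by She (4.71 ± 0.43), Ebf3 (4.61 ± 0.34), the imprinted growth factor gene Igf2 (4.18 ± 0.47), Pou4f1 (4.05 ± 0.28) and Ndnf (4.05 ± 0.38), with edgeR adjusted p from 0.00021 to 0.0018. With the same limit the other largest decreases, beside Mbp, were of Eif3j2 (−4.81 ± 1.21), the myelin gene Mobp (−3.24 ± 0.70), Enpp6 (−2.66 ± 0.55), an enzyme gene of newly forming oligodendrocytes. They were followed by Rinl (−2.54 ± 0.47), Cbln2 (−2.49 ± 0.39), Myo7a (−2.45 ± 0.35), Gng4 (−2.21 ± 0.38), Ppp1r16b (−2.21 ± 0.23) and Alox5 (−2.16 ± 0.43), with adjusted p from 0.00084 to 0.035. Eif3j2 has a near-identical copy, Eif3j1, so its counts are uncertain. The increases, Myo7a and Ppp1r16b kept their calls without each library. Without iOL Eed cKO replicate 1 the calls of the other 7 decreases ended, at adjusted p from 0.0517 (Gng4) to 0.158 (Eif3j2). The calls of Eif3j2, Mobp, Enpp6, Rinl and Alox5 ended without either control library too (0.0511 to 0.163), and all of these but Rinl without iOL Eed cKO replicate 2 (0.0634 to 0.226).

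In all, 959 genes were higher and 475 lower in Eed cKO iOLs. Of these 185 and 24 changed by over 4-fold, and 3142 had an unadjusted p under 0.05. Leaving out a library left 243 higher and 106 lower (iOL control replicate 1), 352 and 140 (control replicate 2), 377 and 81 (Eed cKO replicate 1) or 355 and 176 (Eed cKO replicate 2). All 4 iOL libraries came from day 6 brains. With postnatal day as a term in the fit of all 9 libraries, which acts here through the spread of the OPC libraries, the counts were 1770 and 910.

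Lists of myelin, committed oligodendrocyte and cholesterol synthesis genes were lower in cKO iOLs. Of 19 myelin structural genes 9 fell and 10 did not pass (14 adjusted over the list alone, camera adjusted p = 5.1e-14), with a median log2 fold change of −1.85. Gjb1, a gap junction gene, fell by 3.19 ± 0.37 on the log2 scale, Pllp by 1.77 ± 0.27 and Fa2h, an enzyme gene of myelin lipids, by 1.87 ± 0.31. Of 19 genes of differentiation-committed and immature oligodendrocytes 13 fell, 1 rose and 5 did not pass (15 and 2 adjusted over the list alone, camera adjusted p = 2.5e-18), among them the receptor Gpr17 (−1.82 ± 0.21), the kinase genes Sgk1 (−1.32 ± 0.12) and Fyn (−1.29 ± 0.15) and Zfp488 (−1.45 ± 0.17). Of 24 cholesterol synthesis genes 6 fell and 18 did not pass (15 adjusted over the list alone, camera adjusted p = 6.45e-08), with Hmgcs1 at −0.71 ± 0.16 and Mvd at −0.68 ± 0.16. The adjusted p with an estimated correlation was 0.218, 0.126 and 0.243 for these 3 lists, so none of the 3 calls held with it. Of 22 OPC genes 6 rose, 2 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.253). Rlbp1 (1.23 ± 0.16) and Cspg5 (0.94 ± 0.16) rose and Neu4 (−1.95 ± 0.30) fell, while Pdgfra, the growth factor receptor that marks OPCs, was at 0.41 ± 0.21 (adjusted p = 0.30). Hmgcs1, Mvd and Cspg5 lost their calls without each iOL library in turn (adjusted p 0.0511 to 0.178), and the other genes named here that passed kept theirs.

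The developmental and signalling lists that were higher in cKO OPCs were higher in cKO iOLs too, and so was the BMP target list, which was not called in OPCs. Of 45 developmental transcription factors 23 rose, 1 fell and 21 did not pass (28 and 2 adjusted over the list alone, camera adjusted p = 2.5e-18). Of 10 Hox genes 6 rose and 4 did not pass (10 adjusted over the list alone, camera adjusted p = 2.5e-08), led by Hoxb6 (log2 4.35 ± 0.54) and Hoxa5 (3.93 ± 0.56). As in OPCs, the count limit of the table in part sets the direction and p of the developmental factor and Hox lists. Of 37 Wnt ligands, receptors and modulators 13 rose and 24 did not pass (19 adjusted over the list alone, camera adjusted p = 5.35e-10), including the secreted antagonist Sfrp2 (2.63 ± 0.21), Wnt2b (2.54 ± 0.32) and Wnt7b (1.21 ± 0.15). Of 19 Wnt targets 7 rose, 1 fell and 11 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 1.3e-05), including Lef1 (3.30 ± 0.27) and Ccnd1 (1.40 ± 0.14). Of 20 Notch genes 3 rose and 17 did not pass (7 adjusted over the list alone, camera adjusted p = 0.0028), led by Mfng (2.24 ± 0.37). Of 34 BMP and TGF-beta genes 6 rose, 1 fell and 27 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.019). The 1 that fell was the ligand Bmp4 (−1.58 ± 0.34). Of 15 BMP targets Msx1 (2.47 ± 0.33) and Dlx2 (1.77 ± 0.46) rose and 13 did not pass, with the same count adjusted over the list alone (camera adjusted p = 0.016), and Id1 was at 0.50 ± 0.34. With an estimated correlation the adjusted p was 0.0743 for developmental factors, 0.161 for Hox and for Notch genes and 0.218 for Wnt ligands. It was 0.126 for Wnt targets, 0.368 for BMP genes and 0.246 for BMP targets. The BMP gene list lost its call without iOL control replicate 1 (camera adjusted p = 0.0578) and iOL Eed cKO replicate 2 (0.0519), and the BMP target list without iOL Eed cKO replicate 1 (0.0608). Mfng lost its call without iOL control replicate 1 (edgeR adjusted p = 0.0698), Bmp4 without either control library or iOL Eed cKO replicate 1 (0.0835 to 0.149), and Dlx2 without each of the 4 iOL libraries (0.0783 to 0.259).

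Arrest, secretory and cell-cycle lists were all higher in cKO iOLs. Of 18 senescence and arrest genes 6 rose and 12 did not pass (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.3e-05), with Gas1 at 1.52 ± 0.15, Cdkn2b at 2.52 ± 0.37 and Btg2 at 1.85 ± 0.37. Of 22 secretory genes of senescent cells 8 rose and 14 did not pass (8 adjusted over the list alone, camera adjusted p = 5.3e-06), with Igfbp5 at 3.69 ± 0.49, the chemokine gene Cxcl12 at 3.22 ± 0.30 and Igfbp4 at 2.43 ± 0.26. Of 38 cell-cycle genes 3 rose and 35 did not pass (12 adjusted over the list alone, camera adjusted p = 2.9e-06), and all 38 had a positive log2 fold change with a mean of 0.44. These 3 were Bub1b (0.75 ± 0.18), Rrm2 (0.57 ± 0.15) and Mcm5 (0.53 ± 0.14), and Mki67 was at 0.60 ± 0.36 (edgeR adjusted p = 0.39). The adjusted p with an estimated correlation was 0.0853, 0.222 and 0.326 for the 3 lists. Bub1b, Rrm2 and Mcm5 lost their calls without each of the 4 iOL libraries (adjusted p 0.0633 to 0.302), and Btg2 without all but iOL Eed cKO replicate 2 (0.0666 to 0.127).

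Markers of other cell types moved in cKO iOLs as well. Of 16 pericyte, fibroblast and meningeal markers 4 rose and 12 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.326 with an estimated correlation), namely Igf2, Rgs5 (log2 2.22 ± 0.31), Fn1 (2.35 ± 0.45) and Col6a2 (1.17 ± 0.26), and without iOL control replicate 1 the camera adjusted p was 0.153. Of 37 matrix genes 6 rose, 2 fell and 29 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.0031, adjusted p = 0.326 with an estimated correlation), led by Eln (1.56 ± 0.13). Of 25 neuron markers 5 rose and 20 did not pass (10 adjusted over the list alone, camera adjusted p = 0.00025, adjusted p = 0.326 with an estimated correlation), with Dlx1 at 1.89 ± 0.33. Of 20 immediate early genes 5 rose and 15 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.326 with an estimated correlation), led by Egr3 (2.22 ± 0.27). Of the genes named here Col6a2, Fn1 and Dlx1 lost their calls without iOL control replicate 1 (edgeR adjusted p = 0.168, 0.102 and 0.0687). All 39 ribosomal protein genes failed to pass (mean −0.17, camera adjusted p = 0.022, adjusted p = 0.737 with an estimated correlation). There edgeR gave 0 at an unadjusted p under 0.05, DESeq2 called 0, and the list's call ended without iOL control replicate 1 (camera adjusted p = 0.0860) or iOL Eed cKO replicate 2 (0.0949).

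Other lists were not called in iOLs. The astrocyte markers S100b (log2 −1.58 ± 0.25) fell and Sox9 (0.54 ± 0.15) rose while 17 did not pass (camera adjusted p = 0.308), and Gfap was at 0.92 ± 0.51. Of 6 endothelial markers Kdr (1.32 ± 0.20) and Flt1 (1.87 ± 0.38) rose and Vwf (−0.78 ± 0.18) and Itm2a (−0.63 ± 0.17) fell (camera adjusted p = 0.466). Erbb3 (2.42 ± 0.21) rose and Mitf (−1.33 ± 0.21) fell among 14 Schwann markers (0.533). Tekt1 (1.90 ± 0.34) and Foxj1 (0.71 ± 0.18) rose among 6 ependymal markers (0.0916), and Epop (1.41 ± 0.28) and Phf19 (0.60 ± 0.15) rose among 12 PRC2 subunits (0.703). Mx2 (−1.63 ± 0.28) fell among 13 interferon-stimulated genes (0.251). Cebpb (1.07 ± 0.28) rose and 3 genes led by Vldlr (−0.86 ± 0.16) fell among 19 stress response genes (0.127). Shh (1.58 ± 0.29) rose and Thra (−0.55 ± 0.14) fell among 10 thyroid hormone response genes (0.904). Adjusted over the list alone, the counts of higher and lower members were 1 and 1 for astrocyte, 2 and 2 for endothelial, and 1 and 1 for Schwann markers. They were 2 higher for ependymal, 2 higher for PRC2, 1 lower for interferon, 1 and 3 for stress response, and 1 and 2 for thyroid hormone genes. With the replicate number as a block Thra, Sox9 and Phf19 lost their calls (edgeR adjusted p = 0.0671, 0.0543 and 0.0563). Of the genes named here S100b and Erbb3 kept their calls without each iOL library, and each other one lost its call without iOL control replicate 1 (edgeR adjusted p 0.0540 to 0.343), except Kdr, which lost it without iOL control replicate 2 (0.0502).

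**Figure D3:**
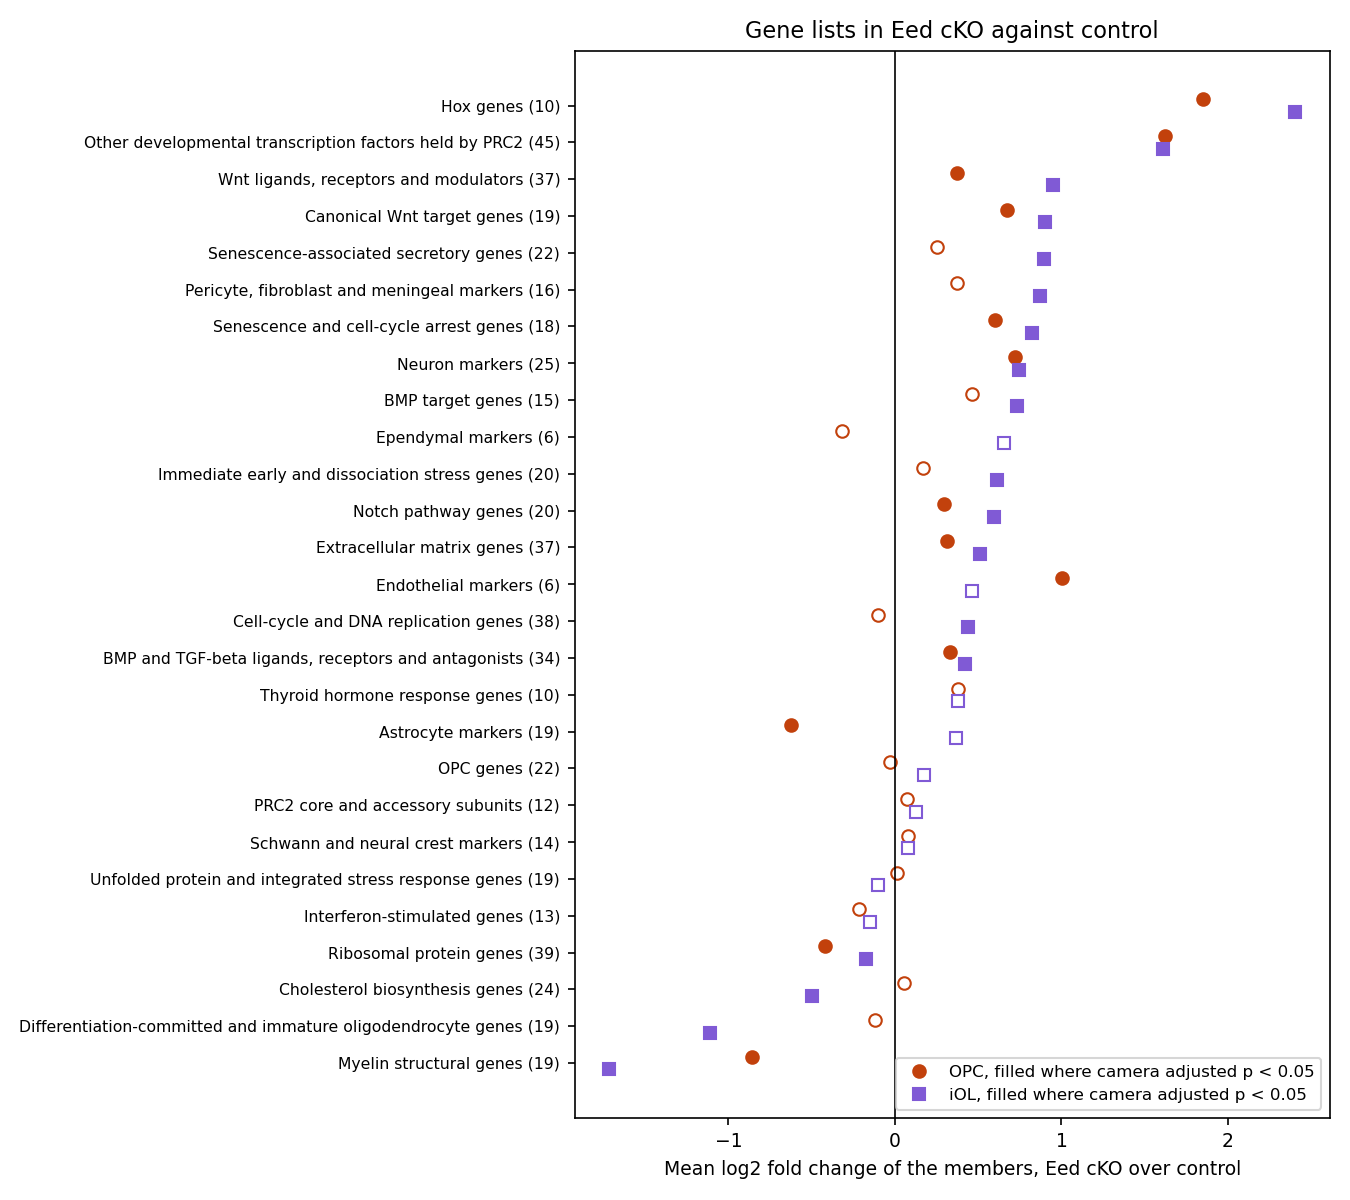
Mean log2 fold change, Eed cKO over control, of the members of each of the 27 tested gene lists, with circles for OPCs and squares for iOLs; the number of measured members stands in parentheses and symbols are filled where the camera adjusted p with the preset correlation passed 0.05. Hox genes (1.85 in OPCs and 2.41 in iOLs) and developmental transcription factors (1.62 and 1.61) have the highest means, and myelin genes (−0.86 and −1.72) the lowest.

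The effect of Eed cKO in OPCs was set against that in iOLs, from libraries with no overlap. Across the 13549 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.454 and a Spearman rho of 0.235. The 2 comparisons shared 223 higher genes, where 28.2 would be shared by independent lists, and 17 lower genes, where 1.44 would be, while 8 genes were called in opposite directions. Foxf1, Cdkn2a, Tbx15, Tbx18, Pou4f1, She, Lef1 and Igf2 were higher in both and Myo7a and Cnp lower in both. The table holds only genes of 10 or more counts in at least 4 libraries. A gene under 10 counts in every control library is therefore held only if cKO libraries of both stages reach 10. Foxf1, Tbx15 and Tbx18 are such genes. Their shared increase is in part set by that limit, so the numbers for independent lists do not apply to such genes. For the other genes they are a rough guide only. Both comparisons came from 1 fit with a shared estimate of the spread of each gene, so their calls are not independent. Of the 399 genes higher in cKO OPCs, 360 had a positive log2 fold change in iOLs, and of the 41 lower 29 had a negative one. Of the 959 genes higher in cKO iOLs, 753 were positive in OPCs, and of the 475 lower 284 were negative.

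**Figure D4:**
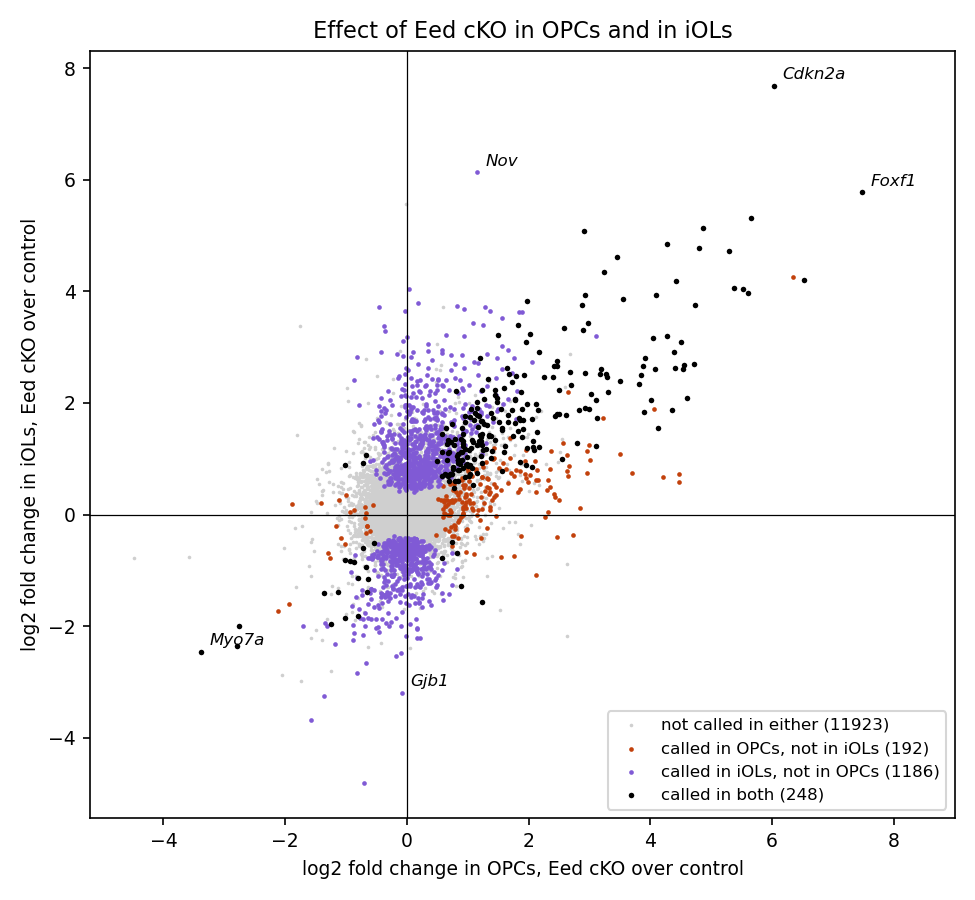
Log2 fold change of each of 13549 genes, Eed cKO over control, in OPCs (horizontal) and in iOLs (vertical), with genes called in both stages in black (248), in OPCs and not in iOLs in orange (192), in iOLs and not in OPCs in purple (1186) and in neither in grey. The Pearson r across genes is 0.454, and Foxf1 and Cdkn2a lie farthest to the upper right.

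Control iOLs were compared with control OPCs to describe differentiation with PRC2 intact. Genes of committed oligodendrocytes rose, 14 of 19 with 5 not passing (15 adjusted over the list alone, camera adjusted p = 3.8e-07, adjusted p = 0.405 with an estimated correlation), including Bcas1 (log2 2.76 ± 0.33) and Cnksr3 (2.44 ± 0.20). OPC genes fell, 12 of 22 with 1 rising and 9 not passing (12 and 1 adjusted over the list alone, camera adjusted p = 2.5e-08), including Cspg4 (−4.04 ± 0.22), which encodes the NG2 proteoglycan, and this call held with an estimated correlation (adjusted p = 0.0337). Of 38 cell-cycle genes 34 fell and 4 did not pass (34 adjusted over the list alone, camera adjusted p = 5.85e-19, adjusted p = 0.274 with an estimated correlation). Of 19 myelin genes 5 rose, 4 fell and 10 did not pass (camera adjusted p = 0.665), with Cldn11 at 3.39 ± 0.60 and Gjb1 at −2.40 ± 0.27. Mbp was already at 1120 to 3467 CPM in control OPCs against 1913 to 2015 CPM in control iOLs.

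In this comparison 2846 genes were higher and 3424 lower, 275 and 698 of them by over 4-fold. The counts were 1801 and 2256 without iOL control replicate 1 and 1784 and 2298 without iOL control replicate 2. The largest increases were of the smooth muscle actin gene Acta2 (log2 8.30 ± 0.39), the acute phase gene Serpina3n (7.86 ± 0.46), C1qtnf1 (7.57 ± 0.31), Prph (6.67 ± 0.41) and Bcl3 (6.56 ± 0.50). They were followed by the imprinted H19 (6.30 ± 0.42), Kcnh1 (6.26 ± 0.43) and Col20a1 (5.80 ± 0.35), with edgeR adjusted p from 2.6e-06 to 1.6e-05. The largest decreases were of the globin gene Hbb-b1 (−10.76 ± 0.89), which has near-identical copies, the immediate early gene Fosb (−8.96 ± 0.44), Rasgrf1 (−6.48 ± 0.27) and C1ql2 (−6.28 ± 0.44). They were followed by Sstr1 (−6.24 ± 0.36), Asic4 (−5.91 ± 0.29), Cd83 (−5.58 ± 0.28) and Sfrp2 (−5.58 ± 0.20). Immediate early and dissociation stress genes were lower as a list, 19 of 20 with 1 not passing (19 adjusted over the list alone, camera adjusted p = 2.1e-17, adjusted p = 0.106 with an estimated correlation). Notch genes (13 lower and 2 higher of 20, camera adjusted p = 8.7e-06, adjusted p = 0.0987 with an estimated correlation) and Wnt targets (9 lower and 3 higher of 19, camera adjusted p = 0.0044, adjusted p = 0.274 with an estimated correlation) were lower, and endothelial markers (2 of 6, Kdr and Vwf, camera adjusted p = 0.0021, adjusted p = 0.106 with an estimated correlation) higher. Adjusted over the list alone these counts were 13 and 2, 10 and 3, and 2. Without OPC control replicate 2 the Wnt target list ended at a camera adjusted p of 0.0522.

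In Eed cKO cultures the same comparison of iOLs with OPCs gave 2505 higher and 2956 lower genes. Of these 267 and 417 changed by over 4-fold. The counts were 1428 and 1816 without iOL Eed cKO replicate 1 or 1280 and 1800 without iOL Eed cKO replicate 2. Its log2 fold changes had a Pearson r of 0.823 and a Spearman rho of 0.771 with those of the controls, from no shared library. There were 1750 genes higher in both (526 from independent lists), 2284 lower in both (747) and 41 in opposite directions. The shared fit and the limit of the table act here too. A gene under 10 counts in every library of 1 stage is held only if libraries of both genotypes of the other stage reach 10. OPC genes fell, 15 of 22 with 2 rising and 5 not passing (16 and 2 adjusted over the list alone, camera adjusted p = 1.5e-08, held with an estimated correlation at adjusted p = 0.0317). Of 19 committed oligodendrocyte genes 4 rose, 2 fell and 13 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.366), with Bcas1 at 1.13 ± 0.28 and Gpr17 at −0.79 ± 0.19. Of 19 myelin genes 2 rose, 6 fell and 11 did not pass (2 and 6 adjusted over the list alone, camera adjusted p = 0.362), with Gjb1 at −5.51 ± 0.34. Of 24 cholesterol genes 15 fell and 9 did not pass (15 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.747 with an estimated correlation), led by Insig1 (−2.12 ± 0.23). Bcas1 lost its call without iOL Eed cKO replicate 2 (edgeR adjusted p = 0.111) and Gpr17 without iOL Eed cKO replicate 1 (0.104).

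The largest changes between cKO OPCs and cKO iOLs were increases of Serpina3n (log2 8.15 ± 0.39), Acta2 (7.45 ± 0.31), Prph (7.08 ± 0.31), Bcl3 (6.45 ± 0.38), Tagln (6.25 ± 0.37), Hpgd (5.76 ± 0.30), S1pr3 (5.56 ± 0.45) and Fn1 (5.40 ± 0.44). The largest decreases were of Hbb-b1 (−11.48 ± 0.94), Fosb (−8.21 ± 0.39), Unc13c (−5.73 ± 0.33), Gjb1 (−5.51 ± 0.34), Klf2 (−5.49 ± 0.61), Tmem255b (−5.42 ± 0.26), C1ql2 (−5.29 ± 0.42) and the antisense gene B9d1os (−5.12 ± 0.30), whose counts are uncertain as for Vax2os, with edgeR adjusted p from 1.9e-06 to 0.00013. Cell-cycle genes (31 lower and 1 higher of 38, camera adjusted p = 1.3e-10, adjusted p = 0.434 with an estimated correlation), and immediate early genes (17 lower of 20, camera adjusted p = 1.5e-16, adjusted p = 0.103 with an estimated correlation) were lower. Notch genes (13 lower and 1 higher of 20, camera adjusted p = 4.6e-06, adjusted p = 0.0979 with an estimated correlation) and Wnt targets (11 lower and 3 higher of 19, camera adjusted p = 0.00097, adjusted p = 0.21 with an estimated correlation) were lower too. Pericyte, fibroblast and meningeal markers (6 higher and 1 lower of 16, camera adjusted p = 0.00046, adjusted p = 0.434 with an estimated correlation) and endothelial markers (2 higher and 2 lower of 6, median 0.18, camera adjusted p = 0.013, adjusted p = 0.21 with an estimated correlation) were called higher. Adjusted over the list alone the lower members of the first 4 lists numbered 32, 18, 13 and 12. Those of the last 2 lists were 6 higher and 1 lower, and 2 higher and 2 lower. The endothelial list was at a camera adjusted p of 0.0700 with postnatal day as a term and 0.0844 with the replicate block, and the adjusted p ranged from 0.000543 to 0.210 over the settings, where the lowest is from the test fry.

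The difference between both differentiation changes, which equals the difference of the Eed cKO effect between iOLs and OPCs, was tested as an interaction. Gjb1 fell further in cKO cultures than in controls (log2 difference −3.10 ± 0.44, edgeR adjusted p = 0.016), while Ndnf, which encodes a secreted neurotrophic factor (4.02 ± 0.50, adjusted p = 0.011) and the Wnt antagonist Sfrp2 (2.29 ± 0.25, adjusted p = 0.011) ended higher. Among committed oligodendrocyte genes, Sgk1 (−1.09 ± 0.16), Zfp488 (−1.53 ± 0.23), Fyn (−1.22 ± 0.20) and Cnksr3 (−1.43 ± 0.27) passed, each with a lower change in cKO cultures than in controls, and among OPC genes Cspg5 (1.35 ± 0.22). With the replicate number as a block Fyn and Cspg5 lost their calls (edgeR adjusted p = 0.0543 and 0.0518). The differences of Mbp (−1.13 ± 0.74, adjusted p = 0.44) and of Cdkn2a were not called. In all, 128 genes had a positive and 120 a negative difference, with 2475 at an unadjusted p under 0.05. These counts were 211 and 167 without OPC control replicate 1, and 1118 and 1038 without OPC control replicate 2. They were 20 and 12, 17 and 9, and 548 and 729 without OPC Eed cKO replicates 1, 2 and 3, 1 and 3 without iOL control replicate 2, and 9 and 4 and 10 and 18 without iOL Eed cKO replicates 1 and 2. Without iOL control replicate 1 edgeR called 0 positive and 2 negative, with 811 and 800 at an unadjusted p under 0.05, whereas DESeq2 on all libraries called 364 and 459. Every one of the genes named here that passed lost its call in at least 1 such case, all of them without iOL control replicate 1 (adjusted p 0.0576 to 0.168).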

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

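The tests of matched random lists, of Lars2 and Mir6236 and of the share of higher calls with postnatal day as a term were chosen only after the result was seen, and the reading of 4 tests was tightened after their values were seen. These were the lineage gene difference, to which leave-one-out values were added, the neighbouring genes, for which lower genes were also counted, the share with postnatal day, for which the count of higher genes was also read, and the chi-square of the control pair, which now needs a larger share of counts in the 2 genes.

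The change from OPC to iOL differed between Eed cKO and control cultures for 128 genes in the positive and 120 in the negative direction, a difference between groups. The largest positive differences were of Crym (log2 4.17), Ndnf (4.02), Fxyd1 (3.63), Fgd5 (3.61), Ntsr2 (3.28), Olfm3 (3.19), Islr2 (2.91) and C1ql1 (2.74). The largest negative were of C1qtnf1 (−3.53), Gjb1 (−3.10), Clcf1 (−3.09), Crybg1 (−2.95), Adamts18 (−2.87), Tle6 (−2.80), Tll2 (−2.57) and Hlx (−2.52). All 40 named calls of this comparison were lost without at least 1 library.

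The lists that differed were myelin (mean −0.86, camera adjusted p = 0.000127, adjusted p = 0.639 with an estimated correlation), committed oligodendrocyte (−0.99, 5.86e-14, adjusted p = 0.615 with an estimated correlation) and cholesterol genes (−0.56, 3.16e-06, adjusted p = 0.615 with an estimated correlation), all lower. Higher were Wnt ligands (0.57, camera adjusted p = 0.000303, adjusted p = 0.639 with an estimated correlation), secretory genes (0.64, 0.000336, adjusted p = 0.615 with an estimated correlation), cell-cycle genes (0.54, 1.0e-08, adjusted p = 0.615 with an estimated correlation), astrocyte markers (0.99, 0.000364, adjusted p = 0.681 with an estimated correlation) and immediate early genes (0.45, 0.0401, adjusted p = 0.681 with an estimated correlation). Most members of these lists, except the committed oligodendrocyte list, were not called singly. DESeq2 called lower 3 of 19 myelin, 12 of 19 committed oligodendrocyte and 5 of 24 cholesterol genes. It called higher 6 of 37 Wnt ligands, 5 of 22 secretory and 2 of 38 cell-cycle genes. Of 19 astrocyte markers it called 4 higher and 1 lower, and of 20 immediate early genes 3 higher. Without OPC control replicate 2 the camera adjusted p was 0.276 for myelin, 0.311 for Wnt, 0.461 for astrocyte and 0.594 for immediate early genes, and the last list also lost its call without OPC Eed cKO replicates 1 and 2 (0.0530 and 0.0619), iOL control replicate 1 (0.329) and iOL Eed cKO replicate 2 (0.0614).

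The myelin list was called lower in cKO iOLs (9 of 19 fell and 10 did not pass, camera adjusted p = 5.1e-14, adjusted p = 0.218 with an estimated correlation), which could come from fewer oligodendrocyte-lineage cells or from less advance of these cells. The median of Olig1, Olig2, Sox10 and Sox8 lay above that of the myelin list by 1.28 log2 units, and by 0.902 to 1.57 without each library. Olig2 (log2 −0.67 ± 0.15) and Sox8 (−0.77 ± 0.13) fell, while Olig1 (−0.06 ± 0.20) and Sox10 (−0.49 ± 0.17) did not pass. The bound set was 1, which the values without each library straddle, so a smaller share of lineage cells stays open. OPC genes were not called higher (camera adjusted p = 0.253), which leaves the other explanation open too.

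OPC control replicate 1 lay apart from OPC control replicate 2, which could reflect postnatal day, maturing cells or ribosomal sequence. The day 7 minus day 6 differences of control and cKO OPCs had a correlation of 0.430, between the bounds set, so day stays open. The myelin list's median ratio lay at percentile 100 of matched random lists, as maturing cells would give, but ribosomal protein genes also lay at 100. Lars2 and Mir6236, entries that overlap ribosomal-like sequence, were at least 15.8-fold above every other OPC library. Without them the chi-square per degree of freedom of the control pair was 93.3, but leaving out 2 genes with 0.96% of the counts of replicate 1 cannot measure ribosomal reads in other genes, so that source stays open.

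More genes were higher than lower in cKO OPCs, which could come from detection limits, from the spread between controls or from lost silencing. Among genes with a control mean of at least 5 CPM 86.5% of calls were higher (230 higher and 36 lower), which argues against detection limits as the only source. Among genes under 5 CPM the share was 97.1% (169 higher and 5 lower), so genes of few counts hold a part of the excess. With postnatal day as a term the share was 61.4% against 90.7%, but higher calls rose too, from 399 to 848, as lower calls rose from 41 to 534, and without OPC control replicate 2 or OPC Eed cKO replicate 3 they were 1862 and 2073 or 1334 and 810, so the spread between controls stays open. Genes called higher formed 24 adjacent pairs on the chromosomes where 11.5 were expected from matched draws (permutation test, p = 6e-04). Lower genes were adjacent in excess as well (2 against 0.115, permutation test, p = 0.006). These 2 pairs were Lims2 with Gpr17 and S100a1 with S100a13, whose positions overlap, which the draws did not take into account. So few pairs weigh little. In cKO iOLs higher genes formed 123 pairs against 66.8 and lower genes 35 against 15.8 (permutation test, p = 1e-04 for both). Adjacency in excess was thus not limited to higher genes, and lost silencing stays open.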

How the results depend on the processing

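Among the genes called in the cKO comparisons and in the difference of differences, none changed sign in any setting. Of the calls of control differentiation 2 had the opposite sign without OPC control replicate 1, while counts of calls moved widely. RLE size factors (408 higher and 37 lower in OPCs, 950 and 479 in iOLs) and the filter of 1 CPM in 4 libraries (397 and 38 in OPCs) moved no count by over 1.5 times, and no filter removed no gene. The replicate numbers were not taken to pair the libraries. In OPCs replicate differences had a correlation of −0.027, which cannot decide on pairing. Control replicates 1 and 2 there are of days 7 and 6, and cKO replicates 1 and 2 are both of day 7. Differences matched by day had a correlation of 0.430. In iOLs a correlation of 0.239 leaves pairing open. The block of replicate numbers joins OPC libraries of different days. Only the cKO OPCs have a replicate 3, so the block gives that library a term of its own. It then adds nothing to the comparisons with the block. With this block the counts were 808 and 284 in OPCs and 194 negative differences of differences, with 8 lists called in OPCs. With postnatal day as a term they were 848 and 534 in OPCs, 1770 and 910 in iOLs and 676 and 526 for the difference of differences. With only the groups compared, a comparison has fewer degrees of freedom and its own estimate of the spread, which the fit of all 9 libraries shares between groups. The counts were then 184 and 6 in OPCs, 2147 and 1552 in iOLs and 1862 higher in control differentiation. The chi-square per degree of freedom was 106 between the control OPC libraries. It was 6.48 between the control and 13.3 between the cKO iOL libraries. DESeq2 gave 767 and 239 in OPCs and 364 and 459 for the difference of differences. The cause was not tested.

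Leaving out 1 library gave 161 to 1862 higher and 3 to 2073 lower genes in OPCs, 243 to 377 and 81 to 176 in iOLs, 1784 to 3221 and 2256 to 4015 in control differentiation, 1280 to 2752 and 1800 to 3137 in cKO differentiation, and 0 to 1118 and 2 to 1038 for the difference of differences, where the 0 came from edgeR without iOL control replicate 1, with 811 positive and 800 negative at an unadjusted p under 0.05 against 364 and 459 called by DESeq2 on all libraries. Lists called ran from 7 to 14 in OPCs, 15 to 19 in iOLs and 5 to 10 for the difference of differences. Of the named calls 32 of 61 in OPCs, 55 of 101 in iOLs, 14 of 116 and 12 of 110 in differentiation and 40 of 40 for the difference of differences ended in at least 1 such case.

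With an estimated correlation camera called 0 lists in OPCs, 0 in iOLs, 1 in control and 1 in cKO differentiation and 0 for the difference of differences, from 13, 18, 7, 8 and 8, with 5, 6, 4, 5 and 1 at an unadjusted p under 0.05. The test fry called 7, 19, 11, 13 and 0, with 10, 20, 13, 14 and 9 at an unadjusted p under 0.05. The correlation of the cKO effects was 0.403 among genes of at least 5 CPM against 0.454, 0.453 with RLE factors and 0.482 with postnatal day.

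Results whose direction turned were Bmpr1a in OPCs (log2 0.59 without OPC control replicate 2, −0.44 without OPC control replicate 1, −0.02 with all libraries), Cd68 in control differentiation (0.75 with postnatal day, −0.02 without), astrocyte markers in cKO differentiation (camera adjusted p = 0.0223 with postnatal day) and ribosomal protein genes without OPC control replicate 1 (0.767 in OPCs, down to 5.67e-27 without OPC control replicate 2, and 0.000708 for the difference of differences, in a range of 3.11e-12 without OPC control replicate 2 to 0.445 without iOL Eed cKO replicate 1). The cause was not tested. Depth of at least 17417529 counts limits genes of few counts, where intervals of ratios are wide. Groups held 2 or 3 libraries, and how far this limits the other results was not measured beyond the simulations.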

Other observations

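The test in this part was chosen only after Dlk1 and Asb4 were seen to be higher. Dlk1 and Asb4, imprinted genes that are active from 1 parental copy, had among the smallest p-values in Eed cKO iOLs. Dlk1 rose by 3.34 ± 0.21 on the log2 scale and Asb4 by 2.80 ± 0.19 (edgeR adjusted p = 0.00021 for both), and in cKO OPCs they rose by 2.58 ± 0.24 and 1.19 ± 0.18. These genes were chosen after their values were seen. PRC2 may hold imprinted genes as a class, which was tested on 45 imprinted genes without these 2 but with Igf2, a gene already named among the largest changes, and H19. Of them 13 were higher and 2 lower in cKO iOLs with a mean of 0.43 (camera p = 0.0126), but p = 0.235 with an estimated correlation. Only 24 of the 45 had a positive log2 fold change there, with a median of 0.24. In cKO OPCs 9 were higher (camera p = 0.000462, 0.131 with an estimated correlation), and 26 of the 45 were positive with a median of 0.18. A rise of the whole class was therefore not shown, and the mean rests on a part of its members.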
